A study of Homo sapiens with 3 samples.

How the data were processed

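The series holds 3 arrays of 293T cells, an established human cell line: 2 after knockdown of TARBP2, each with a different siRNA, and 1 control. Per the labels' protocols, cells grew in medium with 10% serum, were transfected with a lipid reagent, and gave total RNA 48 h later, treated with DNase and labelled with biotin for an Illumina BeadChip. The deposited non-normalized table gives an average signal intensity per probe and array and a detection p-value per probe, per the file headers. Its columns carry the siRNA names. The deposited detection p-values were tied to their arrays by the header order, and each ranked closely against the signal of its own array (Spearman's rho -0.987, -0.985 and -0.984 for siRNA 1, siRNA 2 and control). The authors also deposited a second table of intensity values, which share 1 distribution over the 3 arrays (mean 523 in each; medians 68.5, 68.4 and 68.5), as quantile normalization on a linear scale gives. Another deposited table holds the authors' log fold change (treated as log2, which its header does not state) and a 0 or 1 class per accession. The tool lumi is named in the submitters' processing notes, with version and settings not given in the sources used here. All columns of per-sample values belonged to these 3 arrays.

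The non-normalized signals were background corrected and quantile normalized on the log2 scale with neqc of limma 3.58.1 (R 4.3.3), with the background estimated from the detection p-values and an offset of 16. Probes were named from the platform annotation: 30113 of 47323 probes had 1 gene symbol, 8 had several and 17202 were not listed and stay unnamed here. Of the 30113, 30074 had a gene ID in the RefSeq gene table of assembly GRCh38.p14, used for names only, and 0 symbols needed an update. No genome build is named for the array tables, so no coordinates are given. Of the probes of a gene, the one with the highest mean over the arrays was used, and the gene was kept if that probe had a detection p under 0.01 on at least 1 array. This left 11768 of 20046 named genes. Background correction with a small offset widens differences of dim probes, and quantile normalization hides any change that moves most transcripts together. The arrays differed in mean raw signal (680.4, 514.3 and 528.5), which normalization removed.

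Knockdown was compared with control in limma (lmFit and eBayes, 2 arrays against 1, two-sided) with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The fit had 1 residual degree of freedom and 6.78 prior degrees of freedom, and the median SE was 0.256. Each SE given is this moderated one, drawn mostly from the variance over all genes, and is not the spread of a gene's own arrays. Single siRNAs were set against the control and against each other by a fixed rule of 1.5-fold, with no test. A probe not above background on every array of a group has only a bound there: the fold is then the bright group's mean against, per array, the higher of the probe's own normalized signal and the lowest signal of any detected probe, and is written as at least N-fold. Because both siRNA differences share the control, 100 sets of unchanged arrays were simulated from the fitted variance prior. That prior takes the difference between the siRNAs as error, so it contains any true difference between them and can make the simulated counts and the test's errors too large. The 20 gene lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the lists), and with an estimated correlation as an alternative. That alternative has only the 1 residual degree of freedom. It could hardly call any list, so its lack of calls is no evidence against a list. List medians were also set beside 10000 random lists matched on mean signal in 20 bins, as a description of these arrays.

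The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, except for 3 kinds of alternative: without the small RNAs, the trend and robust fit for TARBP2, and list members picked without the siRNA 2 array. Some tests of explanations in the closing section were also chosen after the results were seen, as stated there. Named are TARBP2, APP and ZNF395, the partners DICER1, AGO2 and PRKRA, and the 12 higher and 12 lower genes with the largest smaller-of-both differences, first those that passed the test. As none passed, all 24 places went to genes ranked the same way without the p criterion, with unnamed and open reading frame symbols skipped. For each list up to 4 members with the largest mean difference are named, and for siRNA 1 against siRNA 2 the 5 highest and 5 lowest genes. PRELID2 and XK, the REST and CTNNB1 genes, PARP9 and IFITM1, and the small RNAs and lists given only in the closing section were chosen after their values were seen.

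The gene lists cover RNA interference machinery, mRNA decay, interferon and double-stranded RNA sensing, ATF4 and the integrated stress response, endoplasmic reticulum chaperones, p53 targets, G1/S, G2/M, histones, ribosomal proteins, oxidative phosphorylation, cholesterol synthesis, glycolysis and hypoxia, heat shock, immediate early genes, lysosomes, miR-17 family targets, and markers of a breast cancer line, of fibroblasts and of the HEK293 lineage. Older symbols were matched through the synonyms of the RefSeq gene table.

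The alternatives were quantile normalization without background correction, an offset of 50, equal array medians in place of quantiles, the authors' deposited normalized values, the mean of a gene's probes, no filter on dim probes, detection on all 3 arrays, eBayes with trend and robust, other thresholds, other list tests, and each siRNA alone. The limma step was tested on simulated data of 11768 genes with 200 changed ones, in 20 runs. At adjusted p under 0.05 it recovered 15% of genes changed 2-fold and 95.9% of those changed 4-fold, with 18.9 false calls per run, and 5.54% of unchanged genes had an unadjusted p under 0.05. Both siRNAs were given the same effect there, and so many changed genes loosen the adjusted threshold. These shares are therefore not the power in these data, where TARBP2 did not pass at a 4.62-fold lower level. A list of 30 genes shifted by 0.3 was called in 20 of 20 runs, and 1 of 380 unshifted lists was called. The simulated genes varied independently of each other, and the shift was larger than the medians of the lists called in the data. These rates therefore do not carry over to the real lists. Figures were drawn with matplotlib 3.10.9.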

Results

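Gene expression was measured in 293T cells, a derivative of the human embryonic kidney line HEK293 that carries the SV40 large T antigen. TARBP2, a double-stranded RNA binding protein that partners DICER1 in microRNA processing, was knocked down with 2 independent siRNAs. Total RNA was taken 48 h after transfection and hybridised to 3 Illumina BeadChip arrays. Each siRNA had 1 array and the control had 1 array. The sample labels call the control an siRNA control, while the series design calls it mock-transfected. Both knockdown arrays form the knockdown group, so the 2 siRNAs are its replicates, and nothing in the labels tells whether they came from separate cultures. P-values of single genes therefore rest on the difference between the 2 siRNA arrays and on the variance over all genes. They hold no spread between control arrays. Camera p-values with the preset correlation set a list's genes against the other genes, so their spread is across genes. Neither kind can tell a knockdown effect from a shift of the lone control array. Raw signal averaged 680.4 on the siRNA 1 array, 514.3 on the siRNA 2 array and 528.5 on the control array, over 47323 probes. Detected probes numbered 19155, 18449 and 18968 in the same order. After normalization, 11768 named genes were above background on at least 1 array. The number of arrays limits the precision of every value given here.

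The labels were checked first on the targeted gene. TARBP2 signal was 2.12 log2 units below control with siRNA 1 (-2.12) and 2.30 below with siRNA 2 (-2.30). The mean difference was -2.21 ± 0.25 (moderated SE, n = 2 knockdown arrays against 1 control array), a 4.62-fold lower level, at probe ILMN_1729767. The other TARBP2 probe, ILMN_2310253, gave -1.63 and -1.85, so both probes and both siRNAs placed TARBP2 below control. In limma's moderated test over all genes TARBP2 had the smallest p (2.79e-05), but its adjusted p of 0.328 did not pass 0.05. It passed where the variance prior was fitted with a trend and robustly (adjusted p = 0.00423; across the alternative settings the adjusted p ran from 0.00423 to 0.490).

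Of the partners of TARBP2, DICER1 and PRKRA lay near control, while AGO2 differed between the siRNAs. DICER1, the RNase that cuts microRNA precursors, differed by -0.05 ± 0.26 (SE, n = 2 against 1). PRKRA, a paralog of TARBP2 that also binds DICER1, differed by -0.07 ± 0.25. AGO2, the slicing Argonaute, was -0.52 with siRNA 1 and 0.26 with siRNA 2. Earlier work in a breast cancer line named the APP and ZNF395 transcripts as destabilized by TARBP2, which makes them a natural question here. APP, the amyloid precursor protein, was 0.31 above control with siRNA 1 and -0.30 with siRNA 2, and the mean difference was 0.00 ± 0.31. Its other detected probes gave means of 0.03 and -0.18. ZNF395, a zinc finger transcription factor, was higher with both siRNAs, by 0.20 and 0.39, with a mean of 0.30 ± 0.25. None of these 5 genes passed the test (limma adjusted p = 0.99991 for each).

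**Figure D1:**
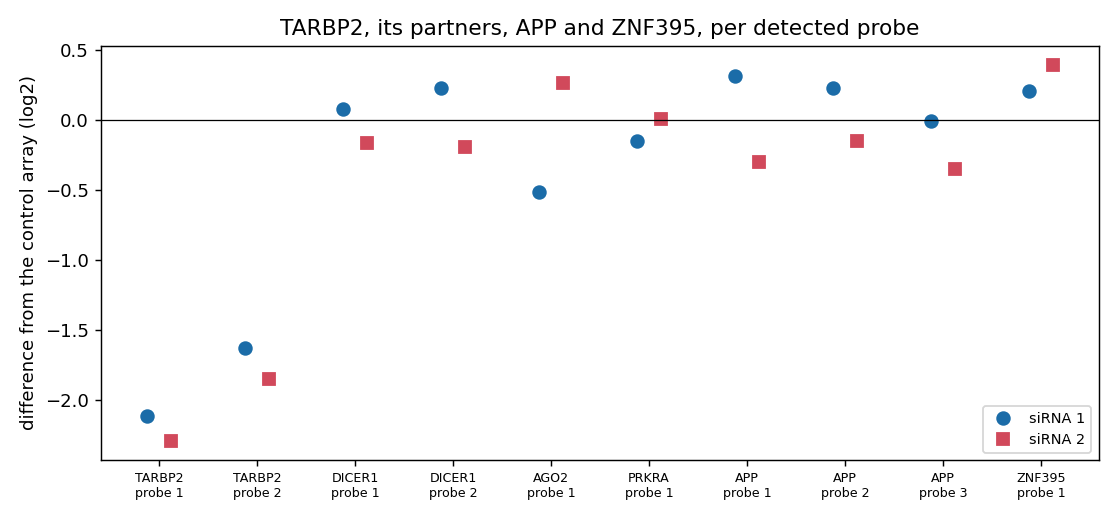
Difference from the control array on the log2 scale (vertical axis) for each detected probe of TARBP2, DICER1, AGO2, PRKRA, APP and ZNF395 (horizontal axis). Circles are the siRNA 1 array and squares the siRNA 2 array, with 1 array each and no error bar. Both TARBP2 probes lie between -1.63 and -2.30, while every other probe shown lies between -0.52 and 0.39.

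Most genes higher with both siRNAs by 1.5-fold had a control signal not above background. The selection itself favours this, so it cannot be read as a trait of the genes. A low reading on the shared control array raises both differences, and detection on 1 knockdown array was enough to keep a gene. The small offset also widens differences of dim probes. DACH2, a dachshund-family transcription regulator, showed the largest mean difference of the 12 named ones at 1.33 ± 0.39 (SE), with 0.85 for siRNA 1 and 1.80 for siRNA 2. ANKRD34B, an ankyrin repeat gene, was 0.96 ± 0.25 higher, and ISM2, a secreted isthmin, was 0.91 ± 0.25 higher, with 0.58 and 0.44 at its other probes. CYP4F22, a fatty acid hydroxylase of skin ceramide synthesis, was 0.87 ± 0.26 higher. F3, the tissue factor that starts coagulation, was 0.80 ± 0.25 higher at the brighter probe, but its second probe gave -0.23 and 0.36. The other 7 had control signals not above background, so they have only lower bounds. SYT13, a synaptotagmin, was at least 1.49-fold higher, and UNC5A, a netrin receptor, at least 1.55-fold. TAFA4, a secreted chemokine-like protein, was at least 1.56-fold higher and HTR7, a serotonin receptor, at least 1.14-fold. YKT6, a SNARE of vesicle transport, was at least 1.40-fold higher, ST6GALNAC5, a sialyltransferase, at least 1.36-fold, and JUNB, an AP-1 subunit, at least 1.22-fold. The authors' deposited values gave smaller means, 0.85 for DACH2, 0.56 for ANKRD34B, 0.47 for ISM2 and 0.46 for CYP4F22, and for the 7 from 0.34 (YKT6) to 0.53 (UNC5A and HTR7). None of the 12 passed the test (limma adjusted p = 0.99991 for each).

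The lower genes included larger differences. Beside TARBP2 there were GOLIM4, a Golgi membrane protein, at -1.43 ± 0.25 (SE), TRIM16L, a TRIM16-like gene, at -1.41 ± 0.32, and LIN7C, a polarity scaffold, at -1.17 ± 0.25. TRA2A, a splicing regulator, differed by -1.58 ± 0.51, with -2.31 for siRNA 1 and -0.86 for siRNA 2. PPP1R12B, a myosin phosphatase subunit, was at -0.89 ± 0.25 and LYZ, lysozyme, at -0.94 ± 0.25. A further 4 places went to RNAs without a poly(A) tail. RNA28SN5, 28S ribosomal RNA, which ranked directly behind TARBP2, was at least 4.65-fold lower with siRNA 1, where it was not above background, and at -1.40 with siRNA 2. RNA5S9, 5S ribosomal RNA, was at least 1.97-fold lower, and the U1 small nuclear RNA variants RNVU1-18 and RNVU1-7 were at -1.12 ± 0.29 and -1.01 ± 0.26. USP53, of the ubiquitin-specific protease family, was at least 1.63-fold lower. Probes of a gene did not all give this size: the other LIN7C probe gave -0.03 and -0.32, and the others of GOLIM4 gave means of -0.43 and -0.82. With the authors' deposited values RNA28SN5 was at -1.26, USP53 at -0.63, RNVU1-7 at -0.59, RNA5S9 at -0.55 and LYZ at -0.54. Apart from TARBP2, each of these had a limma adjusted p of 0.99991.

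By the test, 0 genes rose and 0 fell in the knockdown against control (limma, Benjamini-Hochberg adjusted p under 0.05). At unadjusted p under 0.05 there were 204 genes, 101 higher and 103 lower, where chance alone would give 588.4. The trend and robust setting of limma called 1 gene, TARBP2. The test rested on 1 residual degree of freedom, from the difference between the siRNAs, and the lone control was assumed to vary as the knockdown arrays do.

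By the rule of size, with no replicate check for either siRNA, 53 genes were higher and 56 lower by more than 1.5-fold with both siRNAs. In 33 of the 53 the control signal was not above background, and in 18 of the 56 both knockdown signals were not. PRELID2, SNORD3C and XK, a count of 3, went in opposite directions by the signals as measured, and of these 1, XK, was above background on all 3 arrays. Separately, siRNA 1 had 148 genes higher and 160 lower, and siRNA 2 had 620 higher and 574 lower. Independent lists of these lengths would share 7.80 higher and 7.80 lower genes. Simulated unchanged arrays that share 1 control, with the spread taken from the difference between the siRNAs, gave 174 higher, 174 lower and 14.1 opposite, from a spread that is too large for the siRNA 1 array. The higher count differed between settings. It was 1 against 15 lower genes without background correction and 2 against 17 with the larger offset, settings that shrink differences of dim probes by construction. With equal array medians it was 16 against 50, where the cause was not tested. With the authors' deposited values it was 0 against 15, near the counts without background correction. Those values kept about the level of the raw signals (medians 68.4 to 68.5, raw 67.3 to 73.7). The same shrinkage of dim probes may therefore apply to them, which was not tested.

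**Figure D2:**
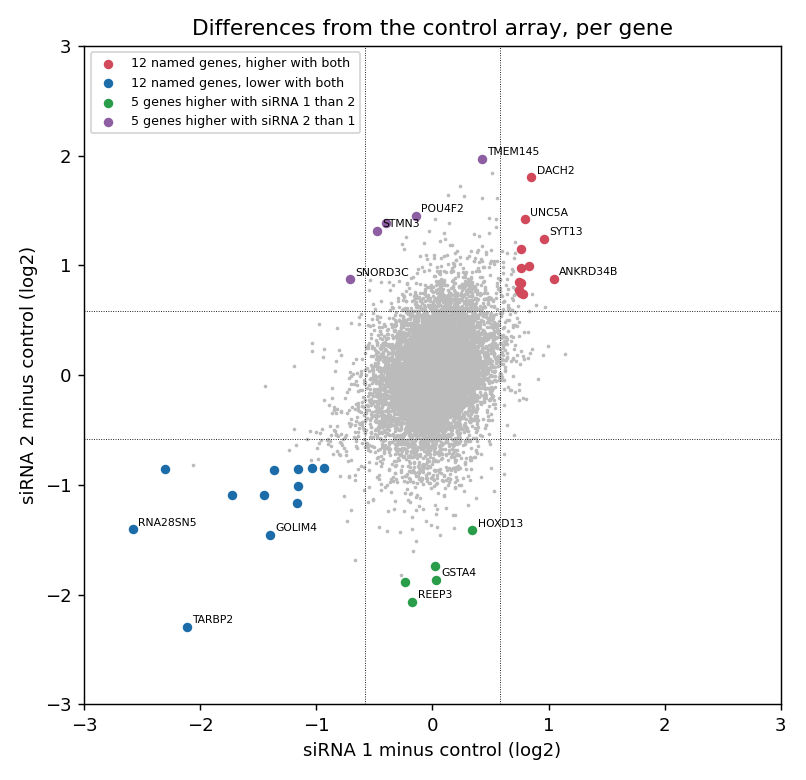
Log2 difference from the control array with siRNA 1 (horizontal axis) and siRNA 2 (vertical axis), 1 point per gene for the 11768 tested genes, as measured and without bounds. Coloured points are the named genes, some with their symbols, and dotted lines mark 1.5-fold. TARBP2 stands apart at -2.12 and -2.30, and the spread is wider along the siRNA 2 axis, with an SD over genes of 0.356 against 0.246 for siRNA 1.

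Over the tested genes the differences with the 2 siRNAs correlated with Pearson's r = 0.320 and Spearman's rho = 0.286, across genes, which are not independent replicates. Arrays that share a control correlate without any effect: the simulated value was 0.4997. The covariance was 0.0280 beside a simulated 0.0661, which is more than the whole variance of the siRNA 1 differences (0.0605). The simulation therefore overstates the spread of the control array, and whether the siRNAs shared an effect across all genes could not be decided from it. The single control array could not be split, and part of any agreement may come from it. The agreement was higher among dim genes: r was 0.452 among the 1655 genes of lowest signal and 0.202 among the 3540 brightest.

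The siRNA arrays differed from each other in many genes. GSTA4, a glutathione transferase, was 1.90 log2 units higher with siRNA 1 than with siRNA 2, DDX46, a splicing helicase, 1.76, HOXD13, a homeobox factor, 1.76, and ERO1A, the oxidase of the endoplasmic reticulum, 1.64. REEP3, which shapes the endoplasmic reticulum, was at least 2.87-fold higher with siRNA 1. In these 5, in the order given, siRNA 1 differed from control by 0.03, 0.02, 0.34, -0.24 and -0.17, and the siRNA 2 array lay below control in each. On the other side, STMN3, a neuronal stathmin, was 3.47-fold higher with siRNA 2 than with siRNA 1, and TMEM145 2.91-fold. CARMIL2, a regulator of actin capping, was at least 2.77-fold higher with siRNA 2 and SNORD3C, a copy of U3 small nucleolar RNA, at least 2.47-fold. POU4F2, a transcription factor of retinal ganglion cells, was at least 2.13-fold higher with siRNA 2. By 1.5-fold, 602 genes were higher with siRNA 1 and 590 with siRNA 2, with no replicate check. With array medians set equal the split was 451 against 993.

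Of the 20 gene lists, 3 fell as groups in the set test with a preset correlation, all by small amounts. None did with an estimated correlation (camera adjusted p = 0.958 for each of the 3), where 1 degree of freedom leaves little room for a call. Genes of the integrated stress response, the program run by ATF4, had a median of -0.14 over 38 measured members. Of these, 21 were lower with both siRNAs, 3 higher with both, and 14 differed between the siRNAs. Within it SLC7A11, the cystine transporter, was at least 1.29-fold lower, ATF5, an ATF4-related factor, was at -0.36 and PHGDH, of serine synthesis, at -0.33, while SLC1A5, a glutamine transporter, was at 0.35. Genes of G1/S and DNA replication had a median of -0.10 over 30 members, 16 lower and 3 higher with both. The siRNA 2 array carried most of this: the median was -0.03 with siRNA 1, at percentile 20.8 of random lists of equal brightness, and -0.16 with siRNA 2, at percentile 0.03. The widest differences were in CCNE2, cyclin E2, at -0.64, RRM2, of ribonucleotide reductase, at -0.53, GINS2, of the replicative helicase, at -0.53, and UNG, uracil DNA glycosylase, at -0.52. The RNA interference machinery, which left out TARBP2 itself, had a median of -0.09 over 23 members, 12 lower and 4 higher with both, with -0.10 for siRNA 1 and -0.06 for siRNA 2. FXR1, a relative of FMRP, was at -0.53, TSN, translin, at -0.50, TNRC6B, an Argonaute partner, at -0.49 and DDX17, a helicase of microRNA processing, at -0.44.

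In camera with a preset correlation of 0.01, the adjusted p over the 20 lists was 0.0300 for the stress response list, 0.0300 for G1/S and 0.0450 for RNA interference. With an estimated correlation none of the 3 passed, but that form had 1 degree of freedom and could hardly call any list. The estimates themselves were -0.001, 0.059 and -0.043 in the same order. With 1 degree of freedom they reflect only how many members were higher on one siRNA array than on the other. They are therefore no check of the preset 0.01. Among the other 8 settings the call for RNA interference ended with equal array medians (adjusted p = 0.0652; range over these settings 0.0288 to 0.0720), with the mean of a gene's probes (0.05025) and with detection on all 3 arrays (0.0720), and that for G1/S ended with the mean of probes (0.05025; range 0.00412 to 0.05025). No member of any of the 20 lists passed, over all genes tested (0) or adjusted over the list alone (0).

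Interferon-stimulated and double-stranded RNA sensing genes had a median of 0.09 over 29 members (0.04 with no filter on dim probes, 0.06 with detection on all 3 arrays) and did not pass (camera adjusted p = 0.0623; 0.958 with an estimated correlation). The median was 0.03 with siRNA 1 and 0.29 with siRNA 2, where it stood at the 99.8th percentile of 10000 random lists of equal brightness, against 64.3 for siRNA 1. IFI44L was at 0.34 and 0.82 with siRNA 1 and siRNA 2 and IFIT2 at 0.42 and 0.49. OAS1, which makes the activator of RNase L, was at -0.45 with siRNA 1 and at least 1.40-fold lower with siRNA 2, where it was not above background. IFI44 was at least 1.07-fold higher over the knockdown arrays. Cytosolic heat shock genes had a median of -0.09 over 17 members (adjusted p = 0.103), with -0.03 for siRNA 1 and -0.22 for siRNA 2. The co-chaperone ST13 was at -0.52 and HSPA1B at -0.32. This list passed under 3 of the settings, without background correction (adjusted p = 0.0464), with the authors' deposited values (0.0420) and with the trend and robust fit (0.0242), with a range of 0.0242 to 0.121 over the 8 settings, but not with an estimated correlation (0.958). Replication-dependent histone genes had a median of -0.15 over 10 members (adjusted p = 0.171), -0.25 with siRNA 1 and -0.07 with siRNA 2, with H2AC11 at -0.35 and H4C14 at -0.28, and passed without a filter on dim probes (0.0458; range 0.0458 to 0.217), but not with an estimated correlation (0.958).

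Target genes of p53 went both ways around a median of 0.03 over 19 members, with 0.01 for siRNA 1 and 0.09 for siRNA 2. PHLDA3, an inhibitor of AKT, was at 0.75 and TNFRSF10B, a death receptor, at 0.48, while TP53INP1 was at -0.66 and MDM2, the ligase that degrades p53, at -0.50. Immediate early genes had a median of 0.13 over 21 members, with 0.07 for siRNA 1 and 0.10 for siRNA 2. Within it the matricellular genes CCN2 and CCN1 were at -0.82 and -0.74, KLF10 was at -0.59, and JUNB was at least 1.22-fold higher. The miR-17 family targets, a readout of microRNA repression, had a median of -0.04 over 28 members, with -0.11 for siRNA 1 and 0.02 for siRNA 2. F3 was at 0.80, RBL1 at -0.78, BMPR2 at -0.67 and TGFBR2 at -0.53. None of these 3 lists passed (camera adjusted p = 0.984, 0.984 and 0.468).

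No list of basal functions passed. Over both siRNAs, medians were -0.02 for mRNA decay factors (DCP2, a decapping enzyme, at -0.61), 0.03 for chaperones of the endoplasmic reticulum (EDEM1 at -0.42), -0.01 for G2/M genes (HMMR at -0.30) and -0.03 for cytosolic ribosomal proteins (RPS21 at -0.45). Oxidative phosphorylation subunits had a median of 0.03 (COX6C at -0.42), cholesterol synthesis genes -0.02 (MSMO1 at -0.48), glycolytic and hypoxia genes 0.02 (ENO2 at 0.45) and lysosomal genes 0.05 (SQSTM1 at -0.36). Cholesterol synthesis was at 0.07 with siRNA 1 and -0.14 with siRNA 2 and ribosomal proteins at -0.05 and 0.00, with the difference of siRNA 1 from siRNA 2 at percentiles 100 and 1.1 of random lists of equal brightness. The sign also differed for G2/M, at -0.06 and 0.004, and lysosomal genes, at 0.02 and -0.01, but there that difference was at percentiles 51.0 and 64.6. With siRNA 1 and siRNA 2 the medians were 0.003 and 0.03 for oxidative phosphorylation, 0.06 and 0.008 for glycolytic and hypoxia genes and -0.03 and -0.02 for mRNA decay. The glycolytic median turned to -0.04 with equal array medians. Marker lists were compared too, though differences from control cannot check what the cells are. HEK293-lineage markers had a median of 0.23 over 8 members (NEFM, a neurofilament, at 0.49). That lay at percentile 99.5 of random lists of equal brightness, against 69.1 with siRNA 1 and 82.1 with siRNA 2. Breast cancer line markers had a median of -0.06 over 9 (ANXA1 at -0.69) and fibroblast markers -0.004 over 4 (FBLN1 at -0.45). With siRNA 1 and siRNA 2 the medians of these marker lists were 0.04 and 0.12, 0.02 and -0.11, and -0.18 and 0.24, and the fibroblast median was 0.02 with no filter. None of these 11 lists passed (camera adjusted p from 0.179 to 0.984). For the immediate early, p53, oxidative phosphorylation and endoplasmic reticulum lists the median was above 0 while the set test pointed down, and the mean was -0.01 for the last of these.

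**Figure D3:**
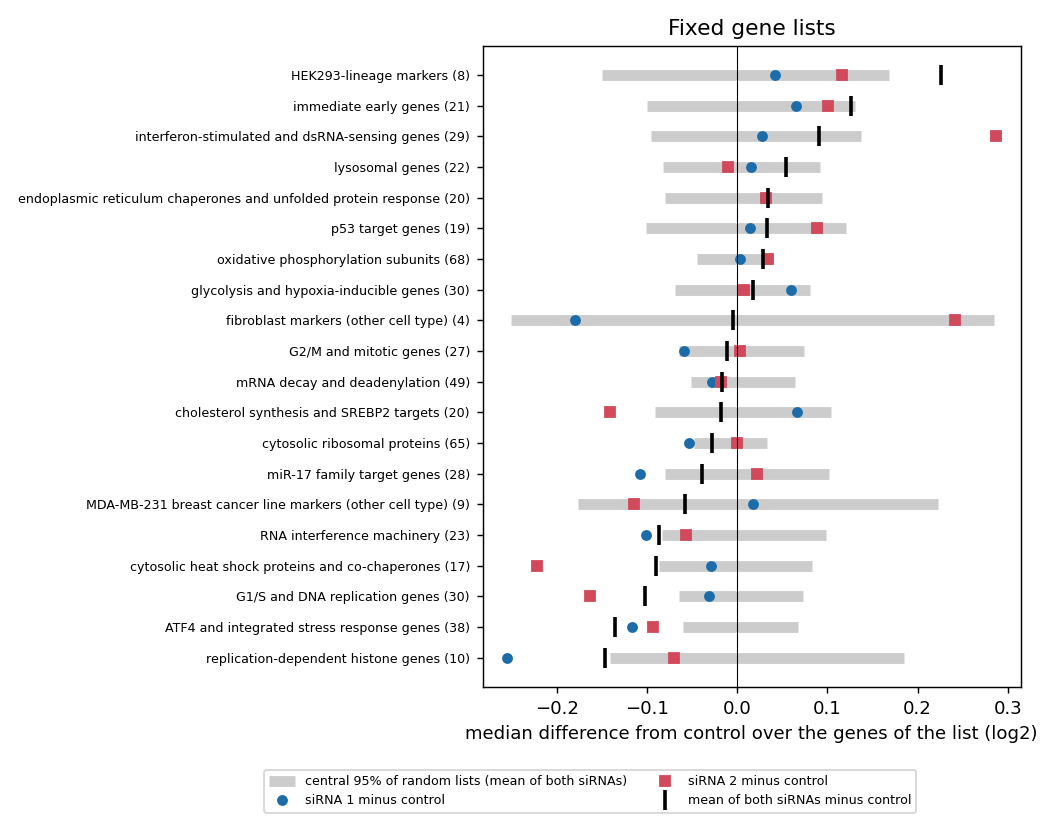
Median log2 difference from control (horizontal axis) for each of the 20 gene lists (vertical axis, number of measured genes in brackets), for siRNA 1 (circles), siRNA 2 (squares) and the mean of both (bars). Grey bands hold the central 95% of 10000 random lists of equal brightness for the mean of both siRNAs. The widest single medians are the interferon list with siRNA 2, at 0.29, and the histone list with siRNA 1, at -0.25.

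The authors' deposited table of their own comparison holds a log fold change for 39747 accessions and places 1036 of them in a higher class, the lowest of these at 0.20003, with no class for lower ones. Its log base is unstated, and its values follow a log2 scale for bright probes (slope 0.991 on the log2 difference of the deposited signals) and a compressed one for dim probes (slope 0.406). In the authors' deposited table the TARBP2 transcripts stand at -1.16 and -0.783, ZNF395 at 0.274, and the APP transcripts at -0.0686 and 0.0189. Over 11575 genes the log fold changes in the authors' deposited table correlated with those computed here (r = 0.864 across genes). Of the 53 genes higher by 1.5-fold with both siRNAs, 18 are in the higher class of the authors' deposited table.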

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

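The set of small RNAs weighed in this part was assembled after its values were seen. PRELID2, a PRELI-domain gene, the XK membrane transporter of the Kell blood group complex and the U3 small nucleolar RNA SNORD3C were singled out because their signals as measured lay past 1.5-fold in opposite directions with the siRNAs. Bounds do not show that size for PRELID2 and SNORD3C. This difference was not tested, as each siRNA had 1 array. PRELID2 was at 0.618 with siRNA 1 and at least 1.28-fold lower with siRNA 2, where it was not above background. XK was at 0.615 and -0.900. SNORD3C was at least 1.348-fold lower with siRNA 1, where it was not above background, and at 0.874 with siRNA 2. Simulated unchanged arrays gave 14.1 such genes, from a spread that is too large for the siRNA 1 array.

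Probes with no single gene in the annotation enter no comparison above. Of 4246 such probes detected on at least 1 array, 25 (0.589%) were higher and 50 (1.18%) lower by more than 1.5-fold with both siRNAs, and 2 went in opposite directions. Of the named genes 0.450% were higher and 0.476% lower with both, and the difference between these shares was not tested. The shares are not like for like: every detected unnamed probe counts, but only the brightest probe of each named gene.

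Over 140 small or ribosomal RNAs without a poly(A) tail, SNORD3C among them, the median was -0.212 with siRNA 1 and -0.0249 with siRNA 2. The median difference between the knockdown arrays was -0.191, lower than in any of 10000 random lists of equal brightness (percentile 0), and the medians differed by 88.2% of the larger one. RNA recovery or labelling that differs from array to array may be a source of the pattern, as that explanation needs such a difference between the knockdown arrays. The gap gives it no specific support, though. The condition set was scaled to the siRNA 2 median of -0.0249, so almost any gap would have met it. Loss of TARBP2 with a like effect of both siRNAs would give like medians, but it cannot be told apart from chance variation between cultures with 1 array per siRNA. U1 variants, 5S, 18S and 28S ribosomal RNA were lower with both siRNAs, and for these neither explanation was tested separately.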

How the results depend on the processing

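Alternatives with the small RNAs left out, the trend and robust setting for TARBP2, and members of the REST and interferon lists picked without the siRNA 2 array, were chosen after seeing the data. TARBP2 stayed below control in every setting run, from -1.67 with the authors' deposited values to -2.21, and from -2.12 to -2.30 with each siRNA alone. It passed the threshold only with the trend and robust fit (-2.21, adjusted p = 0.00423; range over its alternatives 0.00423 to 0.490). That fit called 1 lower gene, and every other setting called 0. The cause was not tested. For genes past 1.5-fold with both siRNAs, the higher, lower and opposite counts of 53, 56 and 3 were 1, 15 and 0 without background correction, 2, 17 and 0 with an offset of 50, 16, 50 and 8 with equal array medians, 0, 15 and 0 with the authors' deposited values, 20, 36 and 1 with detection on all 3 arrays, and 0, 7 and 0 at 2-fold. The filter tests fewer genes and the fold threshold is stricter by construction. Leaving out background correction or raising the offset shrinks differences of dim probes by construction. For the other settings the cause was not tested. All 16 genes of the setting without background correction were among the main 109, and 49 lower genes were left without the small RNAs. Each siRNA alone gave 148 to 620 higher and 160 to 574 lower genes, as a rule on 1 array is less strict. For siRNA 1 against siRNA 2, the counts of 602 and 590 became 339 and 271 without background correction, 365 and 304 with an offset of 50, 334 and 256 with the authors' deposited values, 100 and 70 at 2-fold, and with equal array medians the second became 993. The correlation of 0.320 and covariance of 0.0280 became 0.283 and 0.0152 without background correction, 0.286 and 0.0164 with an offset of 50, 0.256 and 0.0233 with equal medians, 0.278 and 0.0144 with the authors' values, 0.359 and 0.0235 with no filter, and 0.286 and 0.0218 with detection on all 3 arrays. The cause was not tested. In place of 3 lists, 1 was called with the mean of a gene's probes and 0 with an estimated correlation, which left 1 degree of freedom. Outside the central 95% of matched random lists lay 6. Of 200 alternative list medians 192 were counted as keeping their sign, and of 321 alternative values of the other named genes 316 were, with 0 past the threshold. Many of these could not change: the trend and robust fit leaves every difference as it was, and a filter leaves that of a single gene. A ribosomal protein median of 0 with siRNA 2 alone was counted as kept. With members detected on the control or siRNA 1 array the siRNA 2 medians of 0.48 and 0.29 for the REST and interferon lists were 0.44 and 0.27, and with detection on the control array 0.48 and 0.28; the interferon one was 0.17 with no filter. The authors' comparison table holds no values per array, so that alternative was not run, and leaving out a siRNA gave no count of tested genes, as no residual degrees of freedom remain. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Signal over background limits the dim genes: in 33 of the 53 higher genes the control was not above background.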

Other observations

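Of the tests in this part, those on the interferon list, and for the neuronal genes those on loss of TARBP2, on the filter and on cultures or arrays, were chosen after the results were seen, as was the REST target list itself. In a textbook list of targets of REST, the repressor of neuronal genes outside neurons, drawn up without the genes seen among the top differences, 20 of 40 were measured. Their median was 0.48 with siRNA 2 and 0.03 with siRNA 1, and 17 of the 20 were higher with siRNA 2. The siRNA 2 median was 0.28 without background correction, 0.30 with an offset of 50, 0.27 with the authors' deposited values, and 0.24 with no filter, over 38 genes. BSN, a presynaptic scaffold, was at 1.07, SYN1, synapsin, at 0.83, CPLX1, complexin, at 0.77, RUNDC3B at 0.75 and INA, a neurofilament-type protein also on the HEK293-lineage list, at 0.72, while GDAP1L1 was at -0.33 and KIF1A, a kinesin, at -0.19, and SNAP25 was not above background with siRNA 2 or in control. CHGA, a granin of secretory granules, was at least 1.81-fold higher with siRNA 2. In the named genes STMN3, a neuronal stathmin, was at 1.32 and POU4F2 at least 2.08-fold higher. With 1 array per siRNA there is no replicate check. Over both siRNAs the list had a camera adjusted p of 0.00320 with the preset correlation and 0.667 with an estimated one. These were adjusted over the lists of this part alone, so they cannot be set beside those of the 20 lists. The list was drawn up after neuronal genes were seen high on these same arrays, so its p-value gives no independent support. Neural genes not tied to REST, a list of astrocyte and radial glia genes with 12 measured, had a median of -0.20 with siRNA 2, with SOX2 at -0.48 and VIM at -0.34 but NOTCH1 at 0.40, HES1 at 0.36 and NES at 0.33.

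Release of REST target genes may be 1 source of this pattern, as a hypothesis. The list median stood at percentile 100 of 10000 random lists of equal brightness. As the list was drawn up after neuronal genes were seen high on these arrays, that percentile gives the hypothesis no independent support. Without a list of neuronal genes outside REST control, release cannot be told apart from any other rise of neuronal genes. A normalization effect on dim probes is argued against as the whole source of the pattern, since the median lay 0.249 above the central 95% of lists as bright (0.2485). The size did depend on background correction. Over the 19 members detected on the control or siRNA 1 array the distance above such lists was 0.212 with it and 0.0878 without it. A filter that admits genes for a high siRNA 2 signal is argued against too, as those 19 members had a median of 0.44 with background correction. REST mRNA was at -0.26 with siRNA 2 (-0.261) and -0.21 with siRNA 1, too small a difference to decide whether less REST is the source, and 8 measured genes of REST and its corepressors had a median of -0.03. An effect of the siRNA 2 sequence, loss of TARBP2 and a difference between cultures or arrays cannot be told apart with 1 array per siRNA, although the siRNA 1 median stood at percentile 65.6 and the difference between the siRNA arrays at percentile 0.

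Of the 29 measured interferon genes, a list that did not pass over both siRNAs (camera adjusted p = 0.0623; 0.958 with an estimated correlation), 22 were higher with siRNA 2, with IFI44L at 0.82 and IFITM1, chosen after its value was seen, at 0.74, while OAS1 was at least 1.40-fold lower. A widening of dim probes by background correction is argued against as the whole of it: without that step, and over the 27 members detected on the control or siRNA 1 array, the siRNA 2 median of 0.22 still lay 0.0829 above the central 95% of lists as bright. Whether loss of TARBP2 takes part cannot be told with 1 array per siRNA: the siRNA 1 median stood at percentile 64.3 of random lists (64.32), while IFIT2 (0.42 and 0.49) and PARP9 (0.44 and 0.32) were higher with both. A response to the siRNA 2 duplex was not tested, and stays open beside a difference between cultures.

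CTNNB1, beta-catenin, was lower with both siRNAs at both of its probes that were above background on every array. Its brightest probe was at -2.06 with siRNA 1 and -0.82 with siRNA 2, a mean of -1.44 ± 0.46 (SE, limma adjusted p = 0.99991), and the second probe was at -2.01 and -0.89. At the other probe neither knockdown array was above background, and it was at least 1.13-fold lower. The authors' deposited table gives -0.838 for the CTNNB1 transcript.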
